A study of Zea mays with 6 samples.

How the data were processed

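Messenger abundance was measured by RNA sequencing in 6 libraries from whole maize plants treated with Streptomyces sclerogranulatus. The libraries were 3 from susceptible and 3 from resistant plants, 30 days after treatment. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols RNA was extracted with TRIzol; the library steps described there are those of small-RNA preparation, which differs from a gene-level table, and this was left unresolved. The aligner, the counting tool, the genome build, the annotation, the strand setting and the authors' test are not given in the sources used here. Nothing in the labels says that the replicates were grown separately, so p-values measure only the spread between these samples, which may be technical.

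The deposited table gives, for each gene, a read count per library, an FPKM value per library (fragments normalised to gene length and library total by the authors), and the authors' comparison, with an FDR (an adjusted p-value) and a log2 fold change, per the file headers. Every one of its 6137 genes had an FDR of at most 0.009967 and an absolute fold change of at least 1.500 in the authors' deposited table, so genes that did not differ were not analysed here. A pair of rows (2) that continued the annotation of the gene above was left out. The signs of the authors' log2 values matched the counts for 6137 genes, positive where resistant plants were higher.

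Column totals of such a table are not library depths. Relative library totals were recovered from count divided by FPKM over the 3068 genes with at least 100 counts in every library. The design written before the data were examined used TMM normalization, which assumes that most genes do not change. As all listed genes were chosen for changing, the recovered totals replaced TMM in the reported fit. That choice was made after the table had been examined and after the counts of called genes under both scalings had been seen; TMM called 2913 genes higher and 3066 lower, against 2913 and 3224. Normalised counts are counts divided by the relative total.

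Genes were tested with edgeR 4.0.16 (robust quasi-likelihood fit, no covariates) in R 4.3.3, with its default expression filter, which kept all 6137 genes, and Benjamini-Hochberg adjusted p under 0.05. Adjustment over genes that the authors had already selected does not control the false discovery rate of the transcriptome, and no genome-wide enrichment was possible. The common biological coefficient of variation was 0.254. On counts simulated for these 6137 genes with 200 changed, the fit recovered 3.9% of genes changed 1.5-fold, 30.0% of those changed 2-fold and 85.7% of those changed 4-fold, and 8.5% of its calls were false. A planted list was found by camera and 0 of 100 random lists were called. Genes were simulated independently, so this does not test camera on lists whose members are correlated. The weak recovery of small changes applies where most genes do not change.

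The 30 gene lists and the rule for named genes were fixed before the data were examined. Lists were matched to the symbols and descriptions of best protein matches in the table; 4098 genes had an informative description and 173 a maize symbol, and 0 IDs matched the reference gene table, so no coordinates are given. Of the 65 members of the NLR list 13 were other proteins, such as Lr10-type kinases, E3 ubiquitin ligases, a dirigent and a glycine-rich protein. The 28 lists with at least 3 members were tested with camera (preset correlation 0.01, two-sided), which here compares a list only with the other listed genes. Every listed member passed the gene test, over all genes and over its list alone, because of how the table was made. For the same reason no listed gene lay near 0, the smallest absolute log2 fold change being 0.45. A list's median therefore follows the direction of its majority and does not measure a shift of the whole list. Named genes were those with a description: the 4 highest and 4 lowest fold changes with complete separation of the groups and a mean of at least 10 CPM, the 2 members with the smallest p in each of the 6 lists with the smallest camera p, the top member of each other defence list, and the most abundant member of each other organ list. CPM values are relative to the recovered totals, scaled to the mean total of the listed genes. Genes with 0 counts in all 3 libraries of a group and a mean of at least 10 in the other were counted apart.

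Alternatives were TMM, DESeq2 1.42.0 with its size factors, limma 3.58.1 (voom), median-of-ratios and upper-quartile scaling, other filters, the replicate number as a block, each library left out, a minimum effect, other set tests and other ways to match list members. Alternatives added after the data had been seen were the authors' own scaling, a search of Pfam names, Fisher's exact test of direction, a stricter NLR list, and leaving out genes with an absolute log2 fold change above 3 at a preset and an estimated correlation. Replicates of a group differed by far more than counting noise. Permutations and Fisher's exact tests used Python 3.11.15 with scipy 1.17.1.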

Results

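RNA sequencing was carried out on whole maize plants (Zea mays) of susceptible and resistant cultivars, all treated with Streptomyces sclerogranulatus, a filamentous actinobacterium. Plants were collected 30 days after the treatment, with 3 libraries in the susceptible group and 3 in the resistant group. The deposited table held 6137 genes, all of which met the limits of the authors' own comparison, so it described the genes that differed and not the whole transcriptome. Of these, 4581 were gene models and 1556 were new loci added by the authors. Counts in the listed genes came to 8284308, 11053639 and 7167349 in susceptible replicates 1, 2 and 3 and to 8028499, 7193818 and 7755241 in resistant replicates 1, 2 and 3. The totals of the whole libraries, recovered up to a common factor from the ratio of count to FPKM, were 0.869, 1.15 and 0.896 in the susceptible libraries and reached 1.10 in resistant replicate 1, the deepest of its group.

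The comparison asked which genes differed between resistant and susceptible plants after the treatment. Light-harvesting and photosystem genes were mostly lower in resistant plants. Most listed WRKY transcription factors and most members of the receptor-like kinase and NLR lists were higher. Some of the widest contrasts were complete: the new locus NewGene_17548, which resembles a hAT-family transposase, had a normalised read count of 15670 ± 2380 (SD, n = 3) in resistant plants and 0 counts in every susceptible library. The 9-lipoxygenase gene Zm00001eb054050, whose product oxygenates linoleate in the lipoxygenase pathway, was 5.89-fold higher in resistant plants, at 11360 ± 1600 against 1930 ± 318 (SD, n = 3). The chlorophyll a-b binding protein gene Zm00001eb161390, which encodes an antenna protein, was 9.12-fold lower in resistant plants, at 1568 ± 520 against 14290 ± 1950 (SD, n = 3).

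In edgeR's quasi-likelihood test 2913 listed genes were higher in resistant plants and 3224 were lower, and 4385 had an absolute log2 fold change of at least 1. The largest Benjamini-Hochberg adjusted p among them was 0.0458. The authors' deposited table gave the same 2913 and 3224 genes, with a median log2 fold change of 1.80 among the higher genes and -1.43 among the lower ones. Because the table held only genes already called on these 6 libraries, passing the test again was not independent evidence. All plants were treated and no untreated plants were analysed here, so differences between the cultivars and differences in their response could not be separated. Nor could resistance be separated from any other difference between the plants of the groups.

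The 2 groups lay far apart over the listed genes. The first principal component held 95.8% of the variance and the second 1.3%. Pearson correlations across genes, which are not independent replicates, ran from 0.977 to 0.984 within groups and from 0.357 to 0.392 between groups. This separation described genes chosen for differing between the same groups.

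Photosystem and light-harvesting genes formed the list with the clearest direction. Of its 55 listed members 53 were lower in resistant plants and 2 were higher, with a median log2 fold change of -1.04, and all 55 passed when adjusted over the list alone. The antenna gene Zm00001eb161390 had the log2 fold change -3.19 ± 0.27 (SE), with an adjusted p of 1.55e-05 in edgeR. An opposite member was Zm00001eb168820, which resembles the light-harvesting-like protein OHP1; it was at 0 in every susceptible library and at 636.2 ± 96.8 (SD, n = 3) in resistant plants, at least 619-fold higher against a floor of 3 counts over the group. Set against the other listed genes by camera with a preset correlation, the list was lower with an adjusted p of 0.0017. With a correlation estimated from the data the adjusted p = 0.894, so this call rested on the preset value.

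Genes of C4 and Calvin cycle carbon fixation, which assimilate carbon dioxide in the leaf, were lower for 18 of 22 listed members, with a median log2 fold change of -0.69. Phosphoribulokinase, which regenerates the carbon dioxide acceptor of the Calvin cycle, was represented by Zm00001eb072030, 6.42-fold lower in resistant plants at 149.9 ± 29.5 against 962.3 ± 172 (SD, n = 3). A phosphoenolpyruvate carboxylase family locus, NewGene_3882, was 15.9-fold higher, at 118.3 ± 23.8 against 7.428 ± 6.14 (SD, n = 3). The list was not set apart from the other listed genes by camera (adjusted p 0.625).

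**Figure D1:**
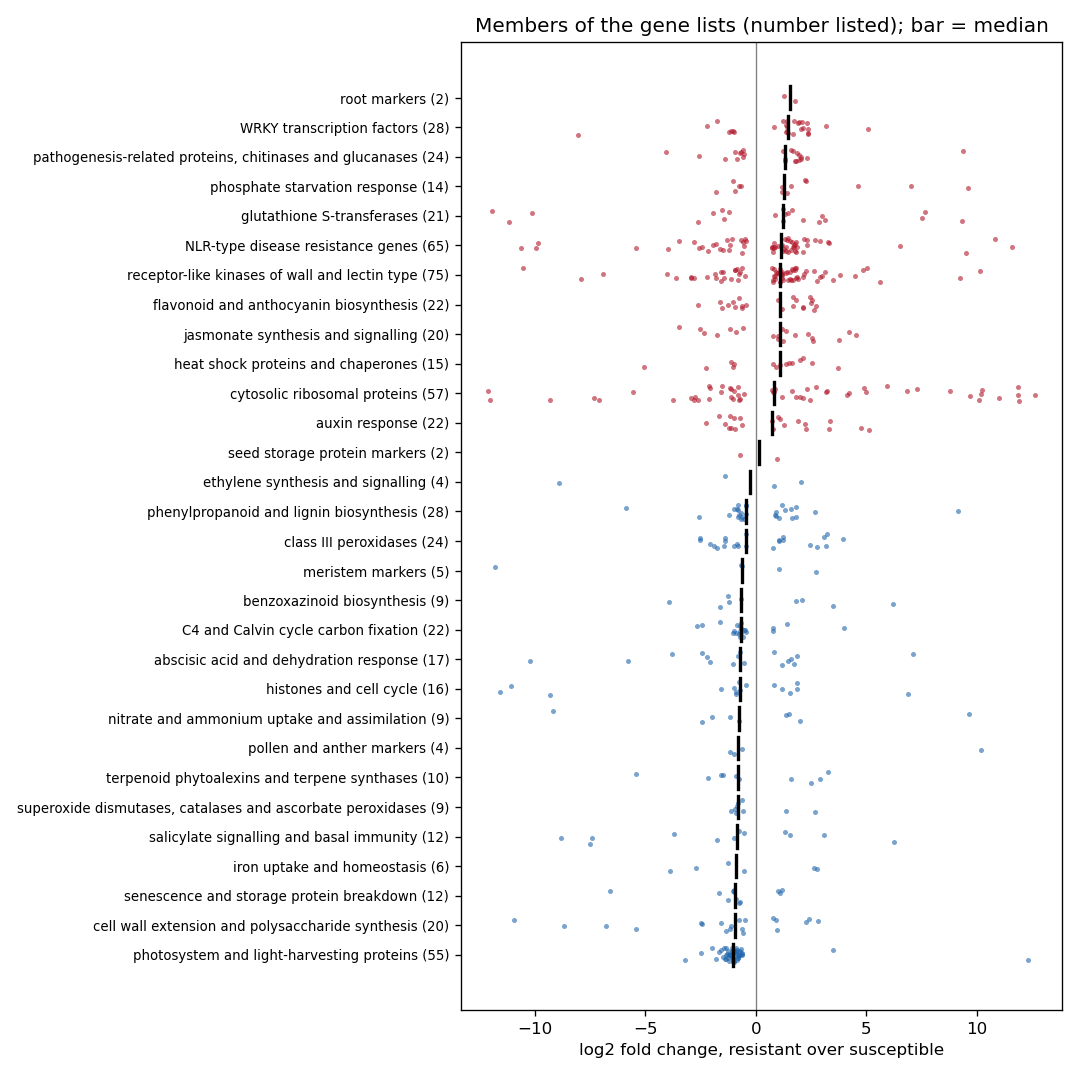
Log2 fold change (resistant over susceptible, horizontal axis) of each member of the 30 gene lists, with the number of listed members in brackets and a black bar at each median; red and blue mark lists with a median above and below 0. Of 55 photosystem members 53 lie below 0, and of 28 WRKY members 21 lie above it. Fitted values of genes at 0 in a whole group depend on the prior count and are not bounds.

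Genes of the WRKY, receptor kinase and NLR lists were more often higher than lower in resistant plants. Among 28 WRKY transcription factors, regulators of many defence genes, 21 were higher and 7 lower, with a median log2 fold change of 1.43. Zm00001eb020400, resembling WRKY transcription factor 4, rose from 5.465 ± 4.21 to 196.8 ± 29.6 (SD, n = 3), a 36.0-fold difference. The new locus NewGene_8092, a putative WRKY protein, went the other way, at 795.5 ± 104 in susceptible plants and 2.974 ± 5.15 (SD, n = 3) in resistant ones.

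Of 75 members of the receptor-like kinase list, 51 were higher and 24 lower, with a median log2 fold change of 1.11. The list was meant for wall and lectin types, which sense cell wall fragments and microbial surfaces. Its search terms also covered leucine-rich-repeat and cysteine-rich receptor kinases, so the counts do not belong to the wall and lectin types alone. Zm00001eb135120, described as wall-associated receptor kinase 2 but closest to the inactive receptor kinase RLK902 in Swiss-Prot, was 8.68-fold higher at 692.8 ± 57 against 79.8 ± 14.9 (SD, n = 3). The leucine-rich-repeat receptor kinase gene Zm00001eb070720 had 461, 529 and 525 counts in the resistant libraries and 0, 2 and 0 in the susceptible ones.

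Of 65 members of the NLR list, meant for intracellular immune receptors, 41 were higher and 24 lower, with a median log2 fold change of 1.14. The list also took in 13 other proteins, among them Lr10-type kinases and E3 ubiquitin ligases. Of the 52 that remained on a stricter list drawn up after the data had been seen, 36 were higher and 16 lower; 3 of these have conflicting descriptions, as an ABC transporter and as the resistance protein RGA4. The RPP13-like gene Zm00001eb304830 was at 0 in every susceptible library and at 380.3 ± 52.3 (SD, n = 3) in resistant plants, at least 370-fold higher. None of the WRKY, receptor kinase and NLR lists passed the camera test against the other listed genes (adjusted p 0.625 for each). NLR and receptor kinase families hold near-identical copies, so reads may have been divided among relatives and single members are uncertain.

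Hormone and defence lists moved in mixed directions. In the jasmonate list 13 of 20 members were higher, and the smallest p belonged to the lipoxygenase gene Zm00001eb054050, with a log2 fold change of 2.56 ± 0.20 (SE) and an adjusted p of 1.03e-05 in edgeR. This gene is a 9-lipoxygenase and not the lipoxygenase of the jasmonate route itself, and KEGG's alpha-linolenic acid pathway, which leads to jasmonate, had 5 listed genes higher and 13 lower (median log2 fold change -0.81). In the list of salicylate signalling and basal immunity 8 of 12 members were lower, yet Zm00001eb420270, resembling salicylic acid-binding protein 2, a methyl salicylate esterase, was 76.3-fold higher at 1080 ± 65.3 against 14.15 ± 2.49 (SD, n = 3). The search terms of the salicylate list also covered MLO-type proteins, so its counts need not belong to salicylate signalling alone. Pathogenesis-related proteins, chitinases and glucanases were higher for 14 of 24 members, while the thaumatin-domain gene Zm00001eb040100 was 5.95-fold lower. Auxin response genes were higher for 12 of 22 members. Genes of abscisic acid and dehydration response were lower for 10 of 17, and the ethylene list had 2 members higher and 2 lower.

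Specialised metabolism also split. Benzoxazinoids are nitrogen-containing defence compounds of grasses; 5 of 9 members of their list were lower, and Zm00001eb373400, resembling the DIBOA-glucoside dioxygenase BX6, was 15.1-fold lower at 42.71 ± 18 against 645.4 ± 122 (SD, n = 3). Terpenoid phytoalexin and terpene synthase genes were lower for 6 of 10 members, among them the acyclic sesquiterpene synthase gene Zm00001eb071090, 4.49-fold lower in resistant plants. Phenylpropanoid and lignin genes were lower for 16 of 28; Zm00001eb188290, resembling a cinnamoyl-CoA reductase, had 163, 181 and 124 counts in susceptible libraries and 3, 5 and 0 in resistant ones. Flavonoid and anthocyanin genes were higher for 12 of 22 members, with a median log2 fold change of 1.10 and a mean of 0.59. As no listed gene lay near 0, a bare majority set that median, and it is not a shift of the whole list.

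Among detoxification and stress lists, 13 of 21 glutathione S-transferases, 11 of 24 class III peroxidases, 10 of 15 heat shock proteins and 2 of 9 superoxide dismutases, catalases and ascorbate peroxidases were higher in resistant plants. Phosphate starvation genes were higher for 9 of 14 members, whereas 5 of 9 nitrate and ammonium genes and 4 of 6 iron genes were lower. Cytosolic ribosomal proteins split into 31 higher and 26 lower, 13 of them at 0 in a whole group. Histone and cell cycle genes were lower for 10 of 16 members. In the list of senescence and storage protein breakdown, whose search terms covered any cysteine protease, 9 of 12 members were lower. The 27 lists other than the photosystem list had camera adjusted p values from 0.625 to 0.833. In the benzoxazinoid, phenylpropanoid, peroxidase and pollen lists the median log2 fold changes (-0.67, -0.46, -0.47 and -0.81) and the camera direction were negative while the means (0.54, 0.22, 0.22 and 1.85) were positive.

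Cell wall genes were lower for 14 of 20 members, with a median log2 fold change of -0.96. The fasciclin-like arabinogalactan protein gene Zm00001eb389410 was at 580.1 ± 75.1 in susceptible plants and 1.21 ± 2.10 (SD, n = 3) in resistant ones. Zm00001eb395860 was at least 251-fold lower in resistant plants; its descriptions disagree, being expansin-like in Swiss-Prot and a betaine aldehyde dehydrogenase in the protein match.

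The lists of organ markers, matched by description, held few genes. Both genes matched by the root list were higher in resistant plants, and Zm00001eb031250, resembling ROOT HAIR DEFECTIVE 3, was 3.37-fold higher at 1453 ± 134 against 431.5 ± 78.5 (SD, n = 3). That protein is a broadly expressed GTPase of the endoplasmic reticulum named for a mutant phenotype, so it does not mark root tissue, and the share of each organ in the samples was not measured. Of 5 meristem markers 3 were lower: the knotted-like homeobox locus NewGene_8173 had 7335, 10725 and 6995 counts in susceptible libraries and 7, 0 and 0 in resistant ones, while the rough sheath 1 match Zm00001eb299420, a regulator of shoot meristems in its family, was 2.07-fold higher. Pollen and anther markers were lower for 3 of 4 members, including Zm00001eb299930 at 1.99-fold lower. The seed storage list had 1 member higher, the legumin-like Zm00001eb355570 at 1.96-fold, and 1 lower.

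**Figure D2:**
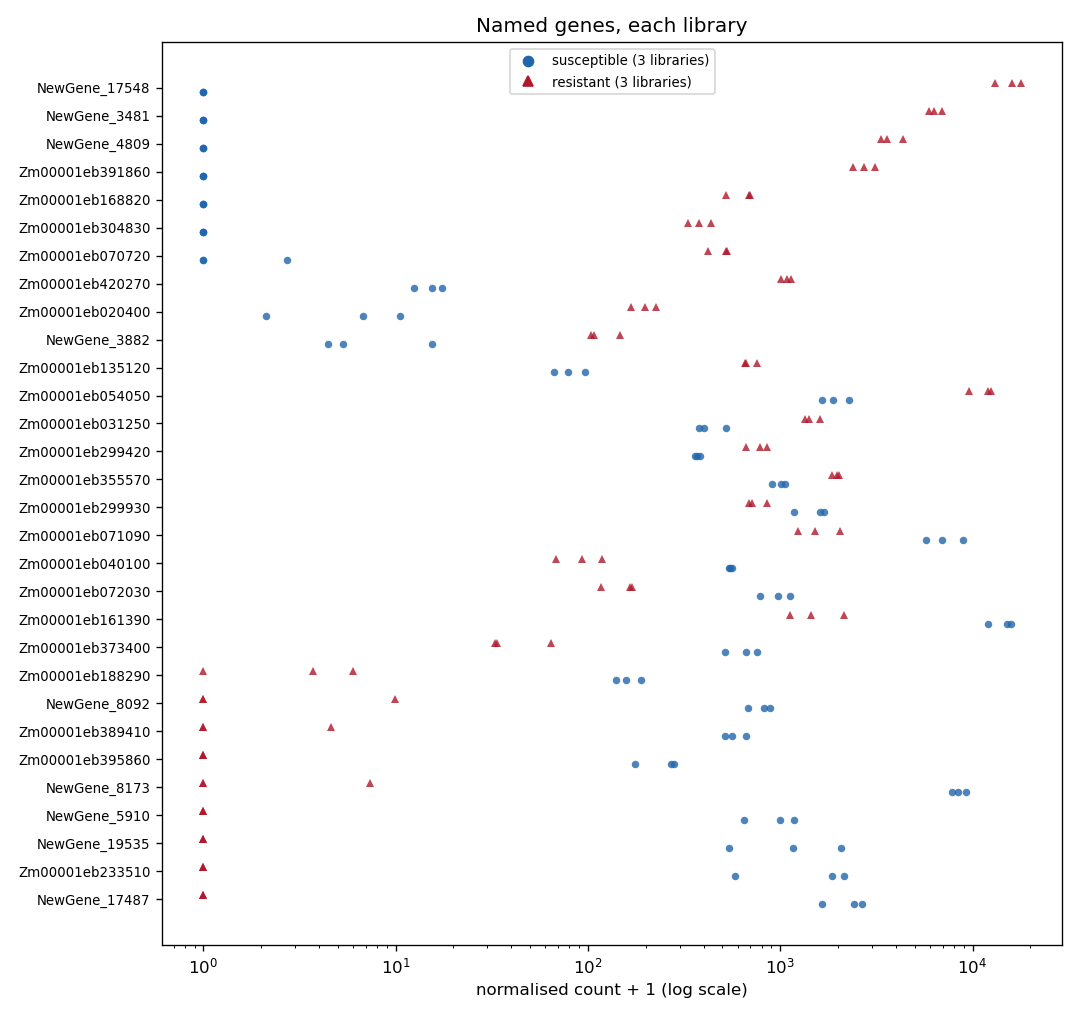
Normalised read count plus 1 (log scale, horizontal axis) of each of the 30 named genes in each library; blue circles are the 3 susceptible libraries and red triangles the 3 resistant ones. For NewGene_17548 every susceptible library is at 0 and the resistant mean is 15670.

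Many listed genes were counted in a single group. In all, 501 genes had 0 counts in every susceptible library and 394 had 0 counts in every resistant library, with median mean counts of 143 and 134.2 in the group that had them. New loci made up 359 of the former and 268 of the latter. Together they were 70.1% of these 895 genes, against 17.7% of the 5242 other listed genes (Fisher's exact test, two-sided, p = 2.01e-210, with genes taken as independent). NewGene_3481, resembling a RICESLEEPER transposase-derived protein, was at least 6250-fold higher in resistant plants, NewGene_4809, a putative NOT complex subunit, at least 3660-fold, and the DEAD-box helicase gene Zm00001eb391860 at least 2660-fold. In the other direction NewGene_17487, a polyprotein, was at least 2320-fold lower, Zm00001eb233510, described as fiber protein Fb15, at least 1590-fold, NewGene_19535, a myb-type locus, at least 1300-fold, and NewGene_5910, resembling UPSTREAM OF FLC, at least 976-fold. These bounds were taken against a floor of 3 counts over the group and cover counting error only.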

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

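Of the alternatives in this part, the authors' scaling, Pfam names, Fisher's test of direction, the stricter NLR list and the removal of large folds were chosen after the data had been seen, as was the reported scaling itself. The 4 other scalings could not turn a sign, as the smallest absolute log2 fold change was 0.45 and they moved the median of all listed genes by only 0.12 (TMM), 0.30 (median of ratios), -0.11 (upper quartile) and -0.13 (the authors' scaling). Genes called higher stayed at 2913 in these scalings, and genes called lower ran from 2444 with median of ratios to 3224. DESeq2 called 2908 higher and 2551 lower, and limma-voom 2909 and 3000. Leaving out each library gave 2912 to 2913 higher and 2961 to 3134 lower. Tested against a minimum absolute log2 fold change of 1, 1882 genes were higher and 1466 lower, fewer by the construction of the test. It took the call from 3 of the named genes and gives no value for lists. The genes counted in a single group came to 490 and 378 with a mean of at least 50 counts, and to 501 to 584 and 394 to 442 without each library. Dropping the filter, or a mean of at least 5 counts, changed nothing.

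The photosystem list lost its call with an estimated correlation (0.894, at a correlation of 0.561) and with members matched by symbol only (0.164, fewer members). It kept the call in the other settings but the last below, and ran from 7.25e-05 to 0.00651 without each library. Only 7 lists had enough members by symbol for a value. Fry, which only asks whether members move 1 way, has little weight on genes chosen for moving. It gave 0.0116 (benzoxazinoids, heat shock), 0.00741 (pathogenesis-related, jasmonate, phosphate, NLR, cell wall, histones, senescence), 0.0288 (flavonoids), 0.011 (salicylate, WRKY), 0.0282 (ethylene), 0.00629 (auxin), 0.0224 (C4, nitrate), 0.0465 (superoxide dismutases), 0.00748 (receptor kinases) and 0.00611 (ribosomal, meristem). Fisher's exact test of direction passed for receptor kinases (0.00578) and WRKY (0.0365). Without genes of absolute log2 fold change above 3, camera gave NLR 0.0448, receptor kinases 0.0495 and WRKY 0.0448, but 0.996 for these and the photosystem list with an estimated correlation; removal by the change under test carries no weight. The planned camera test passed for none of these 3 lists in any planned camera setting.

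The first component held 98.8% with the top 500 variable genes, and the highest correlation between groups was then -0.911, or 0.63 with Spearman over all genes; the cause was not tested. Replicate numbers did not pair the samples: correlations of deviations for the same numbers were 0.008, 0.051 and -0.058. With the replicate block 2913 genes were higher and 3085 lower, and no list changed its call. Of 10 splits of the 6 libraries, 1, the real one, gave 6137 genes and the highest other gave 0; so few splits cannot give a share under 0.05, and the genes were chosen on the real split.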

Other observations

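Tests in this part on pathways, scaling, leaf share, depth, absent genes and the stricter NLR list were chosen after the results had been seen. KEGG pathways of the table were also examined for direction. They can share genes with each other and with the fixed lists, so they do not count as separate findings. Of the 1705 listed genes with a pathway, 46.4% were higher in resistant plants. Among 82 pathways with at least 10 listed genes, plant-pathogen interaction had 96 of 150 genes higher in resistant plants, with a median log2 fold change of 0.92 (Fisher's exact test, adjusted p 0.000262). The pathway of protein processing in the endoplasmic reticulum had 43 of 58 genes higher in resistant plants, with a median log2 fold change of 1.21 (Fisher's exact test against the other listed genes with a pathway, adjusted p 0.000432). Spliceosome genes were higher for 34 of 44 members (adjusted p 0.000666), mRNA surveillance genes for 16 of 18 (0.00239), plant MAPK signalling genes for 51 of 76 (0.00239) and homologous recombination genes for 19 of 24 (0.01). Mismatch repair genes were higher for 12 of 13 (0.00821) and DNA replication genes for 11 of 13 (0.0461). In the fixed list of histones and cell cycle 10 of 16 members were lower, but that list did not pass camera (adjusted p 0.665). Lower in resistant plants were 27 of 31 porphyrin and chlorophyll genes (0.00124), 17 of 18 genes of cutin, suberin and wax synthesis (0.00381) and 27 of 33 genes of glyoxylate metabolism (0.00862), besides all 44 photosynthesis genes (6.6e-11), 23 of 24 antenna protein genes (0.000262), 30 of 39 carbon fixation genes (0.0184) and 20 of 25 genes of other glycan degradation (0.0437). Alpha-linolenic acid metabolism, the pathway of jasmonate synthesis, did not pass (0.393), with 5 genes higher and 13 lower, while the fixed jasmonate list had 13 of 20 members higher. Genes were taken as independent in these tests, which makes the p values too small.

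Lower photosystem genes in resistant plants could come from scaling, from less leaf in the sample, or from the time of day of harvest, besides the cultivars and their response, which the design does not separate. The other scalings left the pattern in place, as at least 87.3% of the members were called lower under each. They could not turn a sign among genes selected for differing, so by themselves they decide nothing. A scaling moves all genes of a library alike, however, and 3.6% of photosystem members were higher against 47.5% of all listed genes. The list's median was -1.04, while the other scalings moved the median of all listed genes by 0.30 at most. These values argue against scaling as the source of the list's direction relative to the other listed genes. Less leaf stays open: 81.8% of C4 and Calvin genes were lower too. The 2 genes matched by the root list (median log2 fold change 1.52) are not established markers of root tissue, so they do not measure root share. For the time of day, 3 dusk-phased clock genes were all lower (median log2 fold change -0.78), while the dawn-phased genes had a median of 1.53 but went both ways, and the LHY-like locus NewGene_6153 among them has conflicting descriptions, so it cannot be told apart from the rest. In KEGG's circadian pathway 19 of 22 genes were lower (adjusted p 0.0121), which also leaves it open.

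For genes at 0 in a whole group, the smallest sum of counts expected there, from the other group and the library totals, was 123.9. The count minimum and the authors' selection keep that sum high by themselves, so it is no test of depth. Runs of neighbouring gene-model numbers fit a hypothesis of segments present in the cultivars of a single group. In 19 of 645 neighbouring pairs both genes were at 0 in the same group, against 1.10 on average in 100000 shuffles (permutation p 1e-05, the smallest they can give). Tandem copies and alleles too far from the reference to be counted could give the same runs, and were not tested.

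The NLR and receptor kinase lists together were higher for 92 of 140 members (65.7%), and with the stricter NLR list for 87 of 127 (68.5%), against 47.0% of the other listed genes. Among the 140 members, 4 were at 0 in every susceptible library and 4 in every resistant library. Genes at 0 in susceptible plants were thus too few to be the whole cause of 92 higher members. For the same reason, leaving such genes out could not remove the excess, so the next values repeat the contrast and are no separate test. Without genes at 0 in a group the shares were 66.7% and 45.5%, an excess of 21.2 percentage points (Fisher's exact p 1.41e-06, genes taken as independent). Genes with a few counts in a group, such as Zm00001eb070720 (0, 2 and 0 in the susceptible libraries), stayed in, so their absence was not tested. Reads shared among near-numbered copies stay open. Members without such a relative had an excess of 14.6 points (Fisher's exact p 0.0134). That met the rule set beforehand, of at least 10 points and a p under 0.05. With its standard error of 5.7, a condition outside that rule, the excess was too near 10 points to exclude shared reads. Partial mismatch of alleles to the reference was not tested, and the planned camera tests of these lists did not pass, so a resistance-linked difference is only a hypothesis.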
